A study of Mus musculus with 8 samples.

How the data were processed

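RNA-seq was done on hearts of mouse embryos at embryonic day 9.5 (E9.5). The labels give 4 samples of the genotype Bmp2GOF;Nkx2.5-Cre (called GOF here, for gain of function) and 4 wild-type samples (WT). Per the labels' protocols, RNA was isolated with an Arcturus kit and libraries were made from polyA RNA with the NEBNext Ultra kit. The labels do not say whether each sample was a single embryo or a pool, nor whether the samples came from separate litters. The p-values therefore measure only the spread between these samples, which may be technical. Xist and the 4 Y-linked genes listed had reads in all 8 samples.

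The authors deposited 1 table of normalized counts, a signal per gene that is never negative, for 13637 Ensembl genes in 8 columns. The submitters' processing notes name CASAVA 1.8.2, cutadapt 1.6, FastQC and RSEM 1.2.3 and the GRCm38 build, with no role or order. The normalization method, the annotation release and any filter on low expression are not given in the sources used here. The values themselves showed more of how they were made. In each column every value equalled a whole number of reads plus 0.5, divided by a single scale per library. The columns summed to between 984298 and 1020939, so a scaling beyond the column total was applied. The share of values that came out whole within a tolerance of 0.01 was 100% in each of the 8 columns. Each gene in the table had a value of at least 1 in at least 4 of the 8 columns, and no value was 0. A level is given below in normalized reads, on the scale of the deposited values. Reads shared between near-identical genes cannot be assigned with certainty from these values. This concerns the Hspa1a and Hspa1b pair, the Hba-a1 and Hba-a2 pair, the H2 genes, and the mitochondrial genes with their copies on chromosome 1. The sources do not say whether reads from the transgene count towards Bmp2.

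The whole reads implied by the values summed to 14703262, 17927674, 13182009 and 14839997 in GOF samples 1 to 4, and to 16697480, 15684958, 12287069 and 13413559 in WT samples 1 to 4. At this depth 3 reads correspond to between 0.17 and 0.242 normalized reads. Limits based on 0 reads use 3 counts over the whole group and cover counting error only. No pair of samples of the same group agreed within sampling noise, with a chi-square per degree of freedom between 3.485 and 18.99 over the genes, so no pair was treated as repeats of the same library. Separately made libraries of the same RNA would differ by more than sampling noise too, so this does not show that the samples are separate embryos.

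Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend and a robust prior), with no covariate. Tests were two-sided, and the threshold was a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The pseudocount of 1 makes a fold change understate the change of low genes. Each adjusted p of a gene given below is from this limma test. A filter of at least 1 normalized read in at least 4 samples removed 0 genes. The design expected that whole reads might allow a count model. The values came out as whole reads in all 8 columns, but 3 of the columns hold too few low values for a separate check of whole reads, so no count model was run and the normalized values stayed the unit tested. Bmp2 was also tested with an exact two-sided permutation test over the 70 assignments of the 8 samples, for which the smallest possible p is 0.0286.

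The tests, the filter, the rule for named genes and 23 gene lists with 437 distinct genes were fixed before the data were examined. The lists came from textbook knowledge and cover BMP response, BMP ligands and receptors, atrioventricular canal, chamber myocardium, cushion mesenchyme and epithelial-to-mesenchymal transition (EMT), Notch pathway, endocardium and endothelium, sarcomere and calcium handling, cell cycle, cell cycle inhibitors, second heart field and outflow tract, sinus venosus and pacemaker, epicardium and proepicardium, erythroid cells, white blood cells and platelets, neural crest, foregut endoderm and liver bud, neural tube, Wnt response, hypoxia and glycolysis, mitochondrial energy metabolism, immediate early and heat shock genes, and sex-linked genes. The sex-linked list was not tested as a list. The other 22 were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Camera compares a list with the other genes, while fry asks whether the genes of a list move on balance in the same direction.

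The genes named below follow a rule. It takes Bmp2, Nkx2-5, Tbx2, Tbx3, Notch1, Hey1, Hey2, Snai1, Nppa, Has2, Tgfb2, Twist1 and Postn in any case. It adds the 10 largest rises and the 10 largest falls past the threshold with no overlap between the groups and a mean of at least 5 normalized reads, and up to 4 members of each list with the smallest p. Any other gene named was chosen after its values were seen, and the text says so. A gene that the rule takes is not reported here. Positions and symbols came from GENCODE M21 on GRCm38, in which 13554 of the 13637 identifiers (99.39%) matched a symbol and 83 did not.

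The limma step was tested on simulated data of the GOF against WT comparison, with 13637 genes and 50 genes changed at each fold. It recovered 42% of the genes changed 1.25-fold, 72% of those changed 1.5-fold, 88% of those changed 2-fold and 96% of those changed 4-fold. There were 6 false calls among 155. Far fewer genes were changed than passed in the data (7679), which makes the adjusted threshold stricter. These rates are therefore not the sensitivity of the real comparison. Alternatives were other pseudocounts, other filters and scalings, limma without trend and robust prior, sample quality weights, a fold threshold of 1.5, leaving out each sample, the replicate number as a block, and the other list tests. Removing GC and length trends, an erythroid covariate, no pseudocount, equal column totals, and leaving out mitochondrial genes were added after the data were seen. Figures were drawn with matplotlib 3.10.9.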

Results

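The expression profile of E9.5 mouse hearts was measured by RNA-seq in 4 GOF samples, in which a Bmp2 gain-of-function allele was combined with Nkx2.5-Cre, and in 4 WT samples. Nkx2.5-Cre drives recombination in cardiac progenitors and their descendants, and Bmp2 encodes a secreted BMP ligand made by the myocardium of the atrioventricular canal. The series title places the comparison in a study of how Bmp2 and Notch act together in patterning the endocardium, the inner lining of the heart. Summed over the genes in the table, the samples held 13182009 to 17927674 reads in GOF and 12287069 to 16697480 in WT. Reads outside these genes are not counted. The first principal component held 72.56% of the variance and separated the groups. The second held 7.98%, and on it GOF sample 1 stood apart at 20.47, against -12.21 to 3.357 for the other GOF samples.

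Bmp2 (ENSMUSG00000027358, protein-coding, plus strand of chromosome 2, 133552159 to 133562885, GRCm38) was higher in every GOF sample than in any WT sample. Its level was 99.1 ± 7.21 normalized reads in GOF (SD, n = 4) and 56.3 ± 5.46 in WT (SD, n = 4). The log2 fold change was 0.81 with a standard error of 0.07 (limma adjusted p = 2.91e-07). The exact permutation test gave p = 0.0286, the smallest that 4 against 4 samples can give. Nkx2-5 (chromosome 17, 26838664 to 26845009, minus strand), the cardiac transcription factor whose regulatory sequence drives the Cre, rose by 0.35 ± 0.07 (log2, SE, limma adjusted p = 0.000421).

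**Figure D1:**
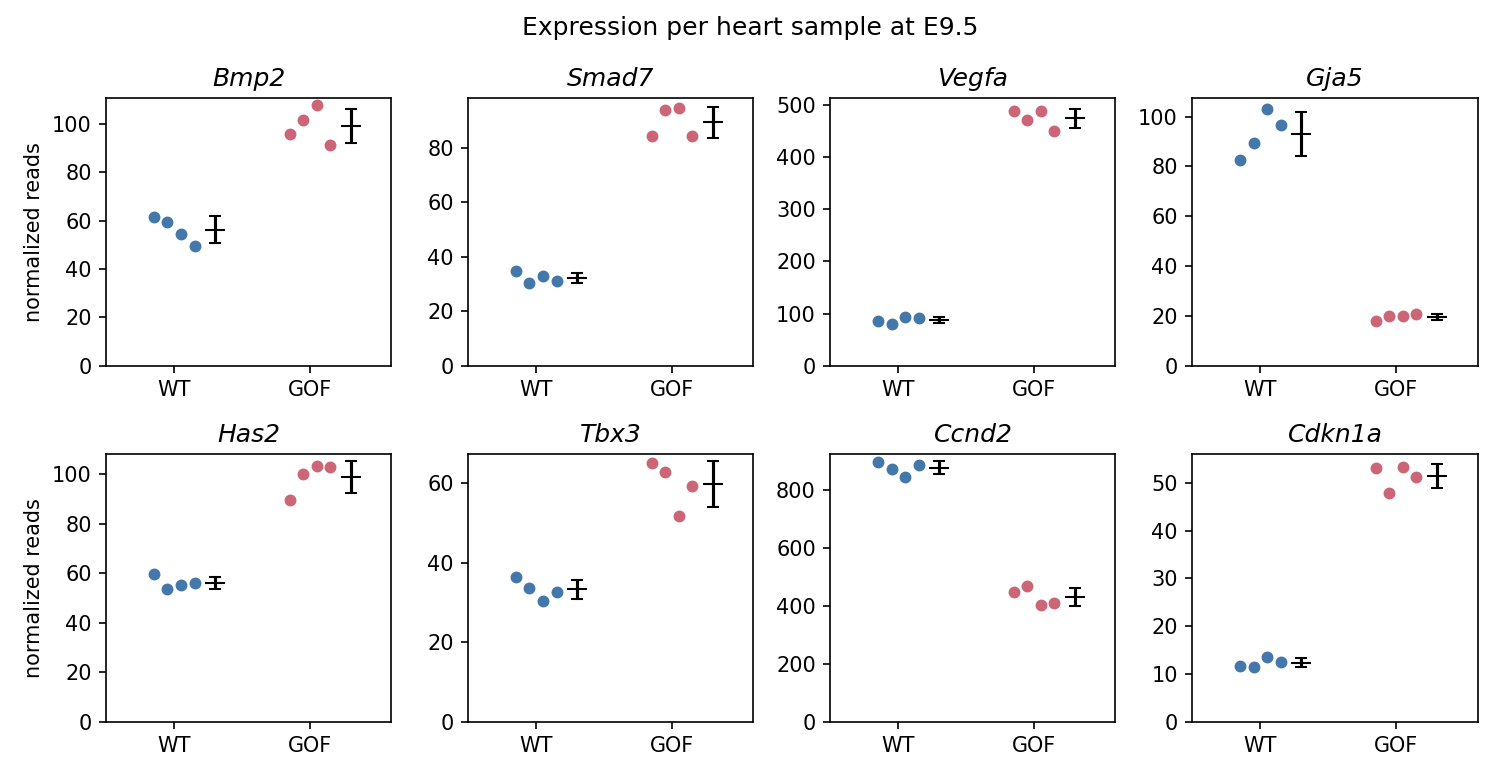
Normalized reads (vertical axes, each from 0) of 8 genes in the 4 WT and the 4 GOF samples. Points are samples and the bars beside them are the mean ± SD. The GOF and WT samples do not overlap for any of the 8 genes, with Bmp2 at 99.1 ± 7.21 in GOF and 56.3 ± 5.46 in WT.

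Expression differed broadly between the groups. Of 13637 genes tested, 7679 (56.31%) passed the threshold, with 3839 higher and 3840 lower in GOF. When mitochondrial genes were left out and columns were set to equal totals, an alternative chosen after the data were seen, 3093 of 7824 called genes (39.5%) were higher. Most changes were small. Rises of at least 2-fold were found for 488 genes and falls of at least 2-fold for 132, and 80 genes rose and 7 fell at least 4-fold. The 4 GOF samples lay entirely above or below the 4 WT samples for 6939 genes (50.88%), against 2.857% by chance.

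The 10 largest rises by the rule for named genes were led by Gm10052 and Ndufa4l2. Ndufa4l2, a mitochondrial protein induced in hypoxia, rose from 2.47 ± 0.588 to 64.4 ± 5.04 normalized reads (SD, n = 4 per group), a log2 change of 4.25. Ndrg1, a hypoxia-induced gene, rose by 4.17. Chac1, which degrades glutathione, rose by 3.95 and Slc7a3, a cationic amino acid transporter, by 3.77. The other large rises were those of Nrn1 (4.14), Sncb (4.07), the immediate early gene Ier3 (3.88), Espn (3.81), A2m (3.55) and the processed pseudogene Gm10052. Gm10052 had 0 reads in the 4 WT samples and 1462 in the 4 GOF samples, which is at least 479-fold higher in assigned reads. A processed pseudogene is a copy of another gene and may share reads with it. Whether transcription of Gm10052 changed was not tested. The limma adjusted p of these 10 genes was 1.52e-05 or smaller.

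The largest falls by the same rule included a gap junction gene and a homeobox gene of the heart. Gja5 (chromosome 3, 96904693 to 97077416), which encodes the gap junction protein connexin 40, fell from 93.0 ± 8.86 to 19.7 ± 1.18 normalized reads (SD, n = 4 per group), a log2 change of -2.18. Irx2, a homeobox transcription factor, changed by -2.01 and Cav3, the muscle caveolin, by -1.86. Kcng1 (-2.56), Igfbpl1 (-2.12) and Acap1 (-2.04) were lower too. The mitochondrial genes mt-Nd4l (-1.85) and mt-Nd1 (-1.84) and Gm28439, an unprocessed pseudogene on chromosome 1 (24611535 to 24612410), also fell. Gm28439 had 0 reads in the 4 GOF samples and 9415 in the 4 WT samples, which is at least 3190-fold lower in assigned reads in GOF. It is a near-identical copy of mitochondrial sequence and may share reads with mitochondrial genes. Whether transcription of Gm28439 changed was not tested. The limma adjusted p of these 9 genes was 6.0e-09 or smaller.

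Genes of the BMP response rose as a list. Of 16 tested members, 10 rose, 2 fell and 4 did not pass, with a median log2 change of 0.32 (camera adjusted p = 0.0252, and adjusted p = 0.3 with an estimated correlation). Without GOF sample 2 or WT sample 4 there was 1 that fell. Smad7, which encodes an inhibitory Smad that restrains BMP and TGF-beta signalling, rose from 32.2 ± 1.96 to 89.3 ± 5.71 normalized reads (SD, n = 4 per group, log2 change 1.44). The inhibitory Smad gene Smad6 rose by 0.75, Smad9, a receptor-regulated Smad, by 1.18 and Bmper, a secreted BMP-binding protein, by 0.71. Of 17 genes for BMP ligands and receptors, 7 rose and 4 fell (camera adjusted p = 0.531). The receptor gene Bmpr1a rose by 0.68 and Smad1 by 0.43, while Bmpr1b changed by -1.25 and Bmp5 by -0.39.

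The atrioventricular canal, where BMP signalling is normally high and the cushions form, was represented by 14 genes. Of these, 10 rose and 2 fell (median 0.34, camera adjusted p = 0.0252, and adjusted p = 0.195 with an estimated correlation). Tbx3, a transcriptional repressor of the chamber program, rose from 33.3 ± 2.44 to 59.7 ± 5.79 normalized reads (SD, n = 4 per group, log2 change 0.82). Has2, the hyaluronan synthase of the cushion matrix, rose by 0.81, Tgfb2 by 0.50 and Cacna2d2, a calcium channel subunit, by 0.56. Tbx2, a related repressor, was at 31.7 ± 4.39 in GOF and 33.8 ± 2.13 in WT, and its change of -0.10 (95% interval -0.28 to 0.08) did not pass the threshold.

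Chamber myocardium genes were lower as a list, with 12 of 22 falling and 6 rising (median -0.29, camera adjusted p = 0.0442, and adjusted p = 0.466 with an estimated correlation). This call was lost without GOF sample 1 (adjusted p = 0.0721) and under other settings given in the closing section. Besides Gja5, the genes Cited1 (-1.34), Stard10 (-1.05) and Smpx (-0.82) fell. Nppa, the atrial natriuretic peptide gene, was at 848 ± 149 in GOF and 753 ± 32.3 in WT (SD, n = 4 per group). Its log2 change of 0.15 did not pass the threshold (limma adjusted p = 0.364), but without GOF sample 1 it was 0.29 (limma adjusted p = 9.44e-06). Hey2, a Notch effector expressed in ventricular myocardium, rose by 0.62. Among 30 genes of the sarcomere and calcium handling, 13 rose and 6 fell (camera adjusted p = 0.449). Myh7, the beta myosin heavy chain, rose by 0.62 and Ldb3 by 0.33, while Myl2, the ventricular myosin light chain, changed by -0.40 and Smyd1 by -0.35.

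Of 29 genes of cushion mesenchyme and EMT, 17 rose and 3 fell (median 0.32, camera adjusted p = 0.0252, and adjusted p = 0.594 with an estimated correlation). Besides Has2, the mesenchymal filament gene Vim rose by 0.57, the N-cadherin gene Cdh2 by 0.47 and Twist1, an EMT transcription factor, by 0.44. Tgfbr3, a TGF-beta co-receptor that takes part in endocardial EMT, changed by -1.64. Snai1, an EMT transcription factor, rose by 0.32 (limma adjusted p = 0.0382), a call lost when GOF sample 2, 3 or 4 or WT sample 1 or 3 was left out (adjusted p 0.0516 to 0.134, and a log2 change of 0.18 without WT sample 3). Postn, which encodes the matrix protein periostin, was at 57.3 ± 28.2 in GOF and 21.8 ± 2.21 in WT (SD, n = 4 per group, log2 change 1.21, limma adjusted p = 0.0395). Its call was lost when any sample except GOF sample 1 was left out (adjusted p 0.0698 to 0.0948).

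The Notch pathway list had 13 genes that rose and 4 that fell among 26 (median 0.16, camera adjusted p = 0.16). With a filter of 5 normalized reads the median was 0.0459, with 10 of 22 higher and 5 lower. It was 0.0882 without mitochondrial genes at equal column totals, and 0.194 without GOF sample 4. Fry, which does not compare the list with other genes, gave an adjusted p of 0.0126. Notch1 was at 70.9 ± 13.7 in GOF and 72.8 ± 4.20 in WT, and Hey1 at 45.1 ± 1.52 and 45.9 ± 4.995 (SD, n = 4 per group). Neither passed the threshold, with 95% intervals of the log2 change of -0.36 to 0.25 for Notch1 and -0.17 to 0.13 for Hey1. The ligand gene Jag2 rose by 0.72 and the coactivator gene Maml1 by 0.48, while the ligand gene Dll1 fell from 7.09 ± 0.0585 to 0.559 ± 0.291. Chosen after their values were seen, the receptor gene Notch3 rose by 0.79 and the ligand gene Dll4 by 0.63, and the ligand gene Jag1 changed by -0.40.

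Endocardial and endothelial markers went both ways, with 7 of 27 rising and 10 falling (camera adjusted p = 0.484). Npr3, a natriuretic peptide receptor of the endocardium, changed by -1.14 and Plvap by -0.80, while Sox17 rose by 1.42 and Klf4, a flow-responsive transcription factor, by 0.80. The epicardium and proepicardium list had 5 of 11 genes higher and 0 lower (median 0.28, camera adjusted p = 0.0442, and adjusted p = 0.637 with an estimated correlation). Krt19, a keratin, rose from 71.3 ± 6.37 to 573 ± 59.5 normalized reads (SD, n = 4 per group), Wt1 by 0.88 and Aldh1a2, a retinoic acid synthesis enzyme, by 1.12. Tcf21 rose by only 0.28 with overlapping groups (limma adjusted p = 0.0146), and lost its call without GOF sample 2 (limma adjusted p = 0.0536). The call of this list was lost without GOF sample 2 (adjusted p = 0.103) or WT sample 1 (adjusted p = 0.0576). Keratin genes also rose in the list of foregut endoderm and liver bud, where Krt18 rose by 1.19 and Krt8 by 1.04 together with Sox17 and Hhex (0.78). In that list 4 of 9 genes rose and 0 fell (camera adjusted p = 0.0646), and it passed the threshold without GOF sample 2 (adjusted p = 0.0161), WT sample 1 (0.0422) or WT sample 4 (0.0443).

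**Figure D2:**
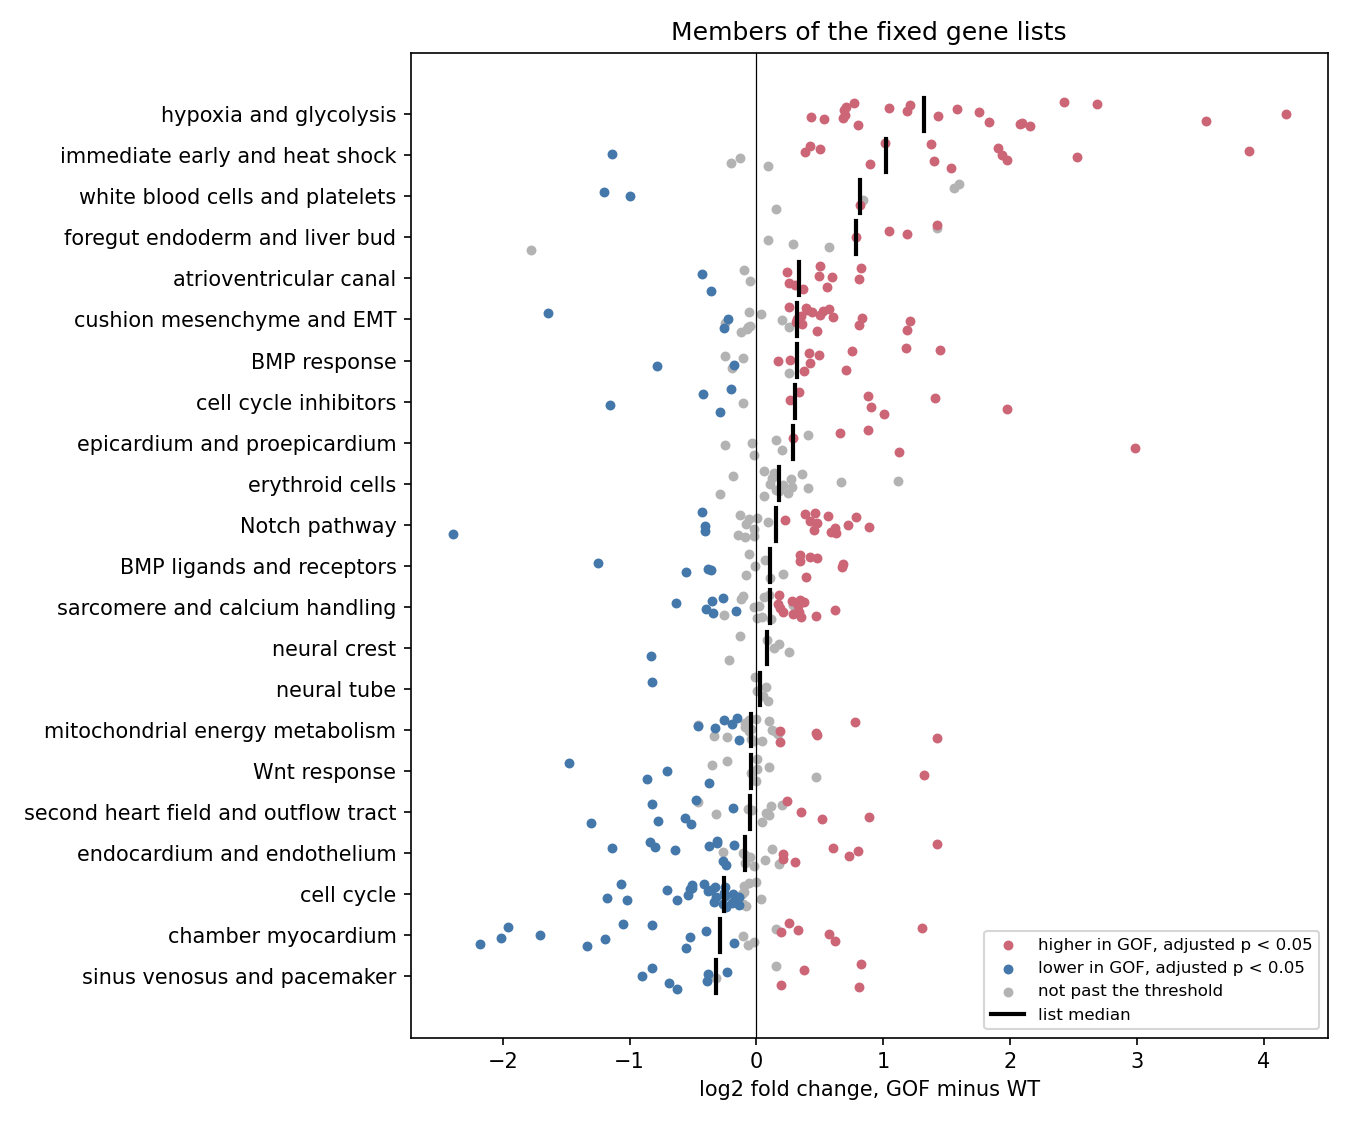
Log2 fold change of GOF against WT (horizontal axis) for each tested member of the 22 gene lists (rows, ordered by median). Each point is a gene, coloured by whether it was higher or lower at adjusted p under 0.05, and vertical bars are list medians. All 22 hypoxia and glycolysis genes lie to the right of 0, and 25 of 33 cell cycle genes passed as lower.

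Hypoxia and glycolysis genes rose in all 22 of 22 tested members (median 1.32, camera adjusted p = 1.12e-17, and adjusted p = 0.195 with an estimated correlation of 0.525). Vegfa (chromosome 17, 46016993 to 46032369), the angiogenic growth factor gene, rose from 87.7 ± 6.53 to 474 ± 18.3 normalized reads (SD, n = 4 per group, log2 change 2.42). Bnip3, a mitophagy receptor gene, rose by 2.09, Egln1, an oxygen-sensing prolyl hydroxylase gene, by 1.83 and P4ha1, a collagen prolyl hydroxylase gene, by 1.75. Immediate early and heat shock genes, which also respond to handling of tissue, were higher in the same samples. Of 17 tested, 13 rose and 1 fell (median 1.02, camera adjusted p = 2.73e-05, and adjusted p = 0.195 with an estimated correlation). Fos rose by 1.98, Junb by 1.90 and Atf3 by 1.53. Erythroid genes, a measure of blood in the hearts, did not pass the threshold in any of 17 members (limma, 0 at adjusted p under 0.05, median 0.18, camera adjusted p = 0.656). The median was not stable, at -0.17 without GOF sample 1, -0.115 without WT sample 1, 0.04 without GOF sample 4 and between 0.22 and 0.47 when any of the other samples was left out, so it gives no direction for blood.

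Cell cycle genes were lower, with 25 of 33 falling and 0 rising (median -0.26, camera adjusted p = 2.83e-09, and adjusted p = 0.195 with an estimated correlation). Ccnd2, the cyclin D2 gene, fell from 875 ± 22.4 to 432 ± 30.8 normalized reads (SD, n = 4 per group, log2 change -1.02). Rrm2, a subunit of ribonucleotide reductase, changed by -1.07, and the replication helicase genes Mcm2 and Mcm4 by -0.71 and -0.52. Among 12 cell cycle inhibitors 7 rose and 4 fell (camera adjusted p = 0.315, fry adjusted p = 3.72e-05). Cdkn1a, the p21 gene, rose from 12.3 ± 0.935 to 51.3 ± 2.48 (log2 change 1.98), Btg2 by 1.001 and Cdkn1b by 0.90. Cdkn1c, an imprinted inhibitor gene, changed by -1.15.

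The remaining lists did not pass. Genes of the second heart field and outflow tract rose in 4 and fell in 7 of 20 (camera adjusted p = 0.484), with Fgf10 (-1.31), Foxc1 (-0.78), Hand2 (-0.56) and Wnt5a (-0.48) lower. In the sinus venosus and pacemaker list 4 of 13 rose and 7 fell (camera adjusted p = 0.531). The calcium channel gene Cacna1h rose by 0.80, while Nr2f1 changed by -0.90 and Cacna1d by -0.62. Of 13 Wnt response genes 1 rose, Dkk3 (1.32), and 4 fell, among them Sfrp5 (-1.48), Dkk1 (-0.87) and Nkd1 (-0.70) (camera adjusted p = 0.531). Without GOF sample 1 or 2 or WT sample 1 or 2 there were 2 that rose. Nuclear genes of mitochondrial energy metabolism rose in 6 and fell in 6 of 28 (camera adjusted p = 0.796). The fatty acid transporter gene Cd36 rose by 1.42, Pdk4 by 0.78 and Cox6a2 by 0.48, while Idh3a changed by -0.46. The median of this list was -0.04 and its mean 0.04, with camera pointing down and fry up. Without GOF sample 1 there were 10 higher and 8 lower and the median was 0.00077, and without mitochondrial genes at equal column totals 11 were lower. Of 7 white blood cell and platelet genes 1 was higher and 2 were lower (median 0.82, camera adjusted p = 0.753). Without GOF sample 1 the median was 0.44 with 2 higher, and without GOF sample 2 there were 3 higher. Lyz2 and Mrc1 changed by -0.998 and -1.21 and Csf1r by 0.82. Pf4, a platelet chemokine gene, was at 25.1 ± 20.9 in GOF and 6.03 ± 0.746 in WT (SD, n = 4 per group), with every GOF sample above every WT sample. Its log2 change of 1.56 did not pass the threshold (limma adjusted p = 0.0584), but without GOF sample 2 it was 2.01 (limma adjusted p = 0.0105, over all alternatives 0.0105 to 0.128), and it passed under other settings given in the closing section. The platelet genes Ppbp and Itga2b, chosen after their values were seen, had log2 changes of 1.59 and 0.84 that did not pass (limma adjusted p = 0.0588 and 0.161). Neural crest genes fell in 1 of 7, Ednrb (-0.83), and rose in 0 (limma, camera adjusted p = 0.87). Erbb3 passed as higher without GOF sample 1 (0.37, limma adjusted p = 0.0121) or WT sample 1 (0.35, limma adjusted p = 0.038), and Ets1 without GOF sample 4 (0.22, limma adjusted p = 0.00539). Neural tube genes fell in 1 of 6, Stmn2 (-0.82), and rose in 0 (limma, camera adjusted p = 0.796). Nes passed as higher without GOF sample 1 (0.13, limma adjusted p = 0.0141). In both of these lists the median was above 0 (0.08 and 0.03) and the mean below 0 (-0.08 and -0.10), and camera pointed down. These medians give no direction. The neural tube median was -0.036 without GOF sample 1, -0.00418 without GOF sample 2 and -0.0448 without WT sample 3, the neural crest median was 0.0371 without GOF sample 2 and 0.0382 without GOF sample 3, and with quantile normalization they were -0.0648 and -0.0479. Adjusted over the list alone, the counts changed for 4 lists. BMP response had 11 higher and 2 lower, Notch pathway 13 and 5, epicardium and proepicardium 4 and 0, and white blood cells and platelets 3 and 2. With an estimated correlation no camera call held at adjusted p under 0.05. Where a list had 0 genes in a direction in the limma test, it also had 0 in that direction at an unadjusted p under 0.05.

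Transcripts of the mitochondrial chromosome, described here after their values were seen, were lower in GOF for 13 of 13 mRNAs. Their log2 changes lay between -0.90 and -1.85 with a median of -1.23. Summed over the 13 mRNAs, the level was 12573 ± 760 normalized reads in GOF and 31089 ± 701 in WT (SD, n = 4 per group, exact permutation p = 0.0286, the smallest possible). The ribosomal RNA mt-Rnr2 changed by -0.53, while mt-Rnr1 rose by 0.70. The transfer RNAs mt-Tn (0.76), mt-Ty (0.71) and mt-Tc (0.61) rose too, and mt-Tl1 (-1.87), mt-Te (-0.98) and mt-Ts1 (-0.65) were lower. These transfer RNAs were at low levels, with group means between 0.735 (mt-Tl1 in GOF) and 16.4 (mt-Ts1 in WT) normalized reads. The groups overlapped for mt-Tc. Reads of the mitochondrial genes are shared with near-identical copies on chromosome 1, so single values are uncertain.

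**Figure D3:**
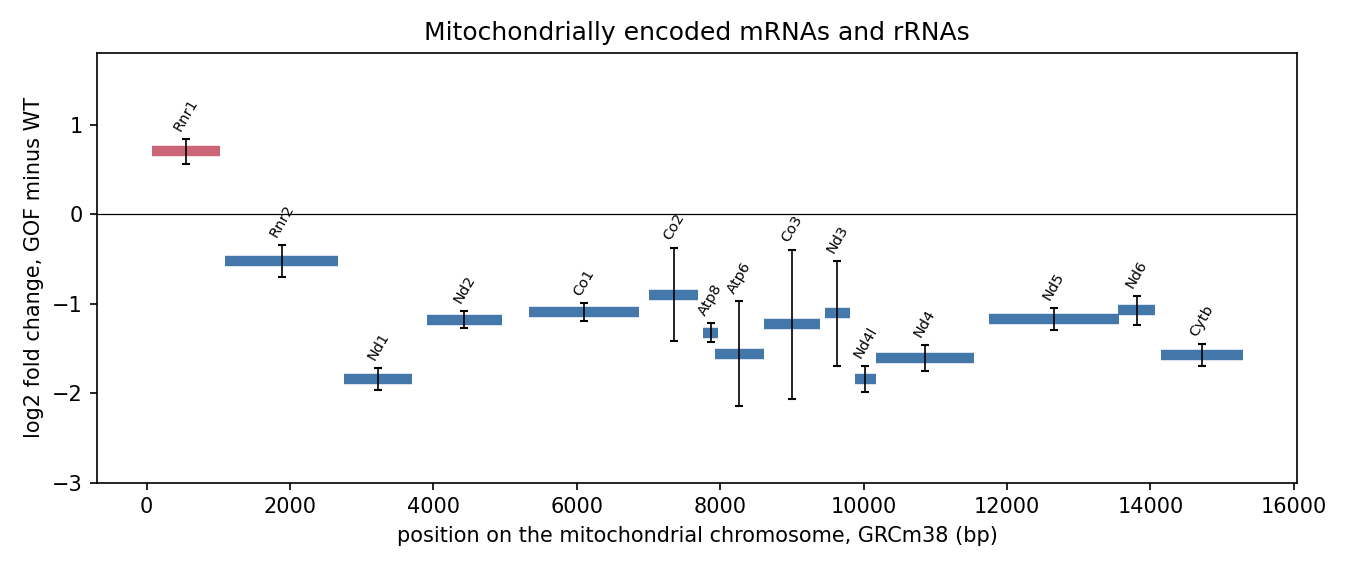
Log2 fold change of GOF against WT (vertical axis) of the 13 mRNAs and 2 ribosomal RNAs along the mitochondrial chromosome (horizontal axis, base pairs, GRCm38). Bars span each gene and whiskers are 95% intervals from limma. The 13 mRNAs lie between -0.90 and -1.85, and mt-Rnr1 lies above 0 at 0.70.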

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

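Each result below was picked out because the highest or lowest of 4 samples lay far from the other 3, with a gap to its nearest neighbour above 0.829 of the group's whole range on the log2 scale. This was the case in 8 of 224 groups, and chance gives about 1 in 20.

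Nppa was at 626.6 normalized reads in GOF sample 1, against 898 to 941.6 in the other GOF samples (gap 0.883 of the range). Without that sample Nppa was called higher in GOF, at a log2 change of 0.29 (limma adjusted p = 9.44e-06, over the samples left out in turn 9.44e-06 to 0.608). GOF sample 1 also stood apart on the second principal component.

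In GOF sample 3, Ier3 was at 125 against 91.22 to 95.76 (gap 0.846) and Cdkn1b at 114 against 102.8 to 103.7 (gap 0.911). In WT sample 2, mt-Nd1 was at 4463 against 4143 to 4173 (gap 0.905) and Gm28439 at 136.3 against 164.5 to 170.6 (gap 0.836). In WT sample 3, Smyd1 was at 601.4 against 585.4 to 587.9 (gap 0.843) and Dkk3 at 122.8 against 109.9 to 111.9 (gap 0.837). In WT sample 4, Stard10 was at 40.94 against 48.21 to 49.28 (gap 0.881). None of these 7 calls changed side when any single sample was left out.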

How the results depend on the processing

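The alternatives without a pseudocount, with equal column totals, with GC and length trends removed, with an erythroid covariate and without mitochondrial genes were chosen after the data were seen. Across 25 alternatives no called gene or list turned its direction, and 49 of 2566 comparisons of the 112 named genes and 31 of 547 comparisons of the lists changed side of the threshold. Requiring a 1.5-fold change left 1830 genes, 1253 higher and 577 lower, since most changes were small. With an estimated correlation 0 lists passed camera, against 8 with the preset value, 4 at an unadjusted p under 0.05, and 11 with fry. Leaving out each sample in turn gave 6983 to 7667 genes, 3540 to 3877 higher and 3439 to 3790 lower, a Bmp2 change of 0.748 to 0.853 and 7 to 9 lists. The chamber myocardium call was lost with a filter of 5 normalized reads (adjusted p = 0.0544), quantile normalization (0.0792), no trend or robust prior (0.0668), equal column totals (0.0523), GC and length trends removed (0.0522), the erythroid covariate (0.0545) and without mitochondrial genes (0.0672). The epicardium call was lost with no trend or robust prior (0.0726) and with GC and length trends removed (0.0522). The foregut list passed with the filter of 5, median centring, quantile normalization, equal column totals and without mitochondrial genes (0.021 to 0.0487). Snai1 lost its call with quantile normalization, no trend or robust prior, equal column totals and without mitochondrial genes (0.0628 to 0.1). The cause was not tested. Quantile normalization gave 43.3% of calls as higher. Testing without a filter changed nothing, since the main filter removed 0 genes, and a count test chosen beforehand was not run, since 3 of 8 columns hold too few low values to check the whole reads separately. Pf4 passed with no trend or robust prior (adjusted p = 0.0252), quality weights (0.042) and GC and length trends removed (0.0449). Replicate numbers 1 to 4 are shared by the groups, but same-numbered samples deviated together by correlations of only -0.13, -0.0188, -0.137 and 0.00674, and no GOF sample correlated best with the WT sample of its own number. With the replicate number as a block, 7355 genes passed, and Snai1 (adjusted p = 0.0612) and Postn (0.0744) did not. In the simulated GOF against WT data 88% of genes changed 2-fold and 72% of those changed 1.5-fold were recovered. Smaller changes were thus missed more often in the simulation. Far fewer genes changed there, with 155 calls against 7679 in the data. Its adjusted threshold was therefore stricter, and its rates do not give the share missed in the real comparison.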

Other observations

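Of the tests in this part, those on GC and length trends, on blood, on handling, on nuclear copies, on a mitochondrial variant, on chromosome 17, on the endoplasmic reticulum and on single embryos, and the amino acid and chaperone lists, were chosen after the results were seen.

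Genes that respond to amino acid shortage rose together in GOF. The large rises of Chac1 and Slc7a3 prompted a list of 24 known genes of this response, including serine synthesis enzymes, amino acid transporters and tRNA synthetases. Without these genes, which prompted the list, all 22 others were higher in GOF, with log2 changes from 0.24 to 3.39 and a median of 1.22 (camera p = 5.82e-15, and p = 0.0544 with an estimated correlation). A general stress of the endoplasmic reticulum, which also turns on many of these genes, would raise its chaperones. Of 12 chaperone genes 0 rose, at an unadjusted p under 0.05 too, and 8 fell (limma, median -0.327, camera p = 0.00881, and p = 0.423 with an estimated correlation), which argues against that explanation. The chaperones bear only on a general stress of this kind. The hypothesis that these genes rose in the GOF hearts without such a stress was found and tested on the same data. Amino acid shortage itself and other triggers of these genes were not tested.

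The difference between the groups was larger than any other split of the samples gave. Of the 35 splits of the 8 samples into 4 and 4, 1 gave as many genes, the real one. The real split gave 7679 genes with limma, and the highest other split gave 0 at adjusted p under 0.05 and 1219 at an unadjusted p under 0.05, against 8261 for the real split. A share of 1 in 35 is the smallest that these splits can give, so they cannot exclude chance beyond that level. Every other split had GOF and WT samples on both sides. The difference between the groups therefore added to the spread within each side and kept the calls of those splits low. Their counts add little to the separation of the groups on the first principal component. A difference between the groups in litter or collection, which the labels do not give, is not excluded by the splits. Nor is a difference in the animals sampled, on which the Xist values below bear.

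The rise of the 22 hypoxia and glycolysis genes was weighed against GC or length bias, blood and handling. With GC and length trends removed, the median stayed at 1.3 and all 22 stayed higher. Log2 changes were nearly unrelated to GC (rank correlation 0.0255) and to length (0.0845), so there was little trend to remove. This argues against such a bias. With the erythroid level as a covariate the median was 1.34, again with all 22 higher. Since 0 of 17 erythroid genes passed between the groups, this covariate could remove little. It argues only against blood as measured by these genes. Immediate early and heat shock genes were higher too, with a median of 1.02, so longer handling of the GOF hearts and a response of the living hearts cannot be told apart, since the labels do not give collection times. A biological effect of the genotype stays open and untested.

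The fall of mitochondrial transcripts was not as a whole a move of reads to the nuclear copies on chromosome 1, since the sum over mRNAs and copies changed by -1.283 on the log2 scale with no overlap between the groups. The losses were uneven, with an SD over the 13 mRNAs of 0.307 against a median standard error of 0.0665. The ribosomal RNA mt-Rnr1 was higher, as were mt-Tn, mt-Ty and mt-Tc at low levels. Of the copies Gm28439 had 0 reads in GOF. Gm29216 rose by 1.18 on the log2 scale (limma adjusted p = 0.00338, higher in 4 of 4 GOF samples than in any WT sample). A mitochondrial DNA variant against the reference may add to such unevenness, and it cannot be told apart from a change in transcript levels here, since the reads were not used and the maternal strain is not given. A lower content of mitochondrial RNA in GOF hearts stays open and untested.

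H2 genes of the major histocompatibility complex lie on chromosome 17 within 10 Mb of Nkx2-5, and were chosen after their values were seen. Of 13 tested 7 rose and 1 fell, with H2-K1 higher by 3.39, H2-Ab1 by 3.44 and H2-Q7 by 2.17, while H2-D1 changed by -0.34 and B2m, on chromosome 2, by 0.49. A block of another strain carried along with Nkx2.5-Cre is a candidate explanation. Within 10 Mb of Nkx2-5, 4.88% of 328 genes changed at least 2-fold, below the 95th percentile of 7.84% around other genes and above the median of 4.22%. This share counts the H2 genes that raised the question, among them H2-K1, H2-Ab1, H2-Q7, H2-Q6 (1.38) and H2-Q2 (1.09). Its place against the median is therefore not independent of them, and a share without them was not computed. Since such a block need change few genes too, the share cannot decide and leaves the block open. The block cannot be told apart here from a rise in the H2 genes.

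Kctd16, chosen after its values were seen, had 0 reads in the 4 WT samples and 155 in the 4 GOF samples, at least 50.8-fold higher. Xist, transcribed from the inactive X chromosome, was at 460 ± 144 normalized reads in GOF and 158 ± 45.2 in WT (SD, n = 4 per group, log2 change 1.53, limma adjusted p = 0.00418, higher in 4 of 4 GOF samples than in any WT sample). Y-linked transcripts were present in the same 8 samples, and the log2 changes of Kdm5d (-0.27), Uty (-0.37), Ddx3y (-0.18) and Eif2s3y (-0.06) did not pass the threshold. Xist and these 4 Y-linked genes were above 10 times the value of 3 reads in 8 of 8 samples, with Xist between 117 and 656 and Kdm5d between 12.1 and 27.4 normalized reads. This argues against samples that each hold RNA of a single embryo and of no other animal. Pooled embryos and tissue of the mother were not tested. Since Xist differed between the groups without overlap, the animals sampled may differ between the groups along with the genotype. For the genes compared here, such a difference was not separated from the genotype.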
